A study of Mus musculus with 20 samples.

How the data were processed

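Gene expression was measured in sciatic nerves of mice at postnatal day 8, with 1 array per animal and 20 animals in 4 groups of 5. The groups, taken from the sample labels, were ErbB2 mutants, their controls, Maf mutants and their controls. All mutants carried Egr2-Cre, a Cre recombinase active in the Schwann cell lineage, and either a pair of floxed alleles or 1 floxed and 1 null allele of the target gene; the controls carried no Cre. Per the labels, total RNA was made into biotin-labelled cDNA and hybridised to a 1-colour Affymetrix mouse whole-transcript array.

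The deposited values were log2 intensities per probe set that the authors made with RMA, a background correction, between-array normalization and probe summary method, and with Partek, with no version or setting given for either. The arrays' medians lay between 8.51 and 8.56 and all values between 2.53 and 15.0, which fits values on the log2 scale already normalised between arrays, so they were used without further scaling. Arrays have no read depth, and their number, 5 per group, limits the precision. The median standard error of a log2 fold change was 0.08 in both comparisons, because all 4 groups share 1 estimate of the spread per gene. The spread itself was not equal. The lowest correlation between arrays of a group was 0.958 among Maf mutants and 0.990 among ErbB2 mutants.

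An exact linear relation tied the means of both lines together in all 35556 probe sets. A least squares fit with genotype class and a 2-level factor left a line term with an SD of 9.40e-06 log2 over probe sets, so the deposited values hold no difference between the lines apart from these terms. A line term subtracted before deposit would leave contrasts within a line unaffected and set the contrast of both control groups near 0. Residual degrees of freedom were not reduced for terms that may have been fitted before deposit.

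Of the 35556 probe sets, the array's table paired 21789 with 1 gene symbol, 1621 with several, and 12146 were not listed in it. Symbols were looked up through the Entrez ID in the RefSeq gene table of assembly GRCm38.p6, which was also used for the order of genes along chromosomes; the array's own genome build is not named, and no coordinate was taken from that table. The lookup found 21698 probe sets, changed 0 symbols, and left 91 symbols as they stood. Where several probe sets named a gene, the one with the highest mean over all arrays was kept, which left 19938 genes. Some genes of the lists, and some of the genes set to be named, were not analysed here.

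The 4 groups entered 1 linear model per gene in limma 3.58.1 under R 4.3.3, with moderated variances that follow a trend on mean expression (eBayes), contrasts of each mutant group against the control of its own line, and the difference between these contrasts. P-values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called changed at an adjusted p under 0.05. Fold changes are mutant minus control on the log2 scale. No batch, litter or sex was given in the labels, and no covariate or block entered the model. No pairing of mutants with controls by the number in a sample's name was seen. Of 10 mutants 0 resembled the control of their own number most, although Maf control 3 resembled Maf mutant 3 most. So few pairs cannot exclude that the numbers mark litters.

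In addition, 25 gene lists were tested with camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, and adjusted over the lists. They covered cholesterol and fatty acid synthesis and their control, myelin components, Schwann cell states, signalling, stress, glycolysis, proliferation, and the other cell types of a nerve and of adjoining tissue. The mean of each list per array was compared by a two-sided exact permutation test of 5 against 5 arrays, whose smallest possible p is 0.00794, adjusted over the lists as well. Correlations of fold changes were taken across genes, which are not independent replicates. Figures were drawn with matplotlib 3.10.9.

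The groups, tests, thresholds, lists and most alternatives were fixed before the data were examined, and so was the rule for the genes named. That rule took Erbb2 and Maf, a fixed set that included Hmgcs1, Sqle, Egr2 and Sox10, up to 10 genes per direction with the largest change whose 5 mutant and 5 control values did not overlap, up to 4 genes per list with the smallest adjusted p, 5 genes per direction for the difference of effects, and 5 per direction shared by both comparisons. Predicted gene models and small RNAs were counted but not named. The alternatives were other variance models, a fit on the groups of a comparison alone, quantile normalization, centring on medians, a filter on low values, other choices of probe set, a replicate block, array weights, stricter thresholds, covariates for muscle and Y-linked expression, flox/flox mutants alone, and leaving out each array. A covariate for each array's interquartile range, one for the 2-level factor, and leaving out Maf mutants 4 and 5 together were added after the data had been seen.

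The model was tested on simulated data with 19938 genes, with normal noise independent between genes and 1 spread per gene for all groups. Of 100 genes shifted by 0.5 log2 it recovered 87 in the design of the ErbB2 comparison and 84 in that of the Maf comparison. Of 100 genes shifted by 1 log2 it recovered 99 and 98, and 14 of 200 calls and 13 of 195 calls were false. The real arrays share variation across genes, so these rates need not hold for them.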

Results

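RNA from sciatic nerves of 20 mice at postnatal day 8 was profiled on whole-transcript arrays, with 5 ErbB2 mutants, 5 ErbB2 controls, 5 Maf mutants and 5 Maf controls. Erbb2 encodes a receptor tyrosine kinase that carries neuregulin signals into Schwann cells together with Erbb3, and Maf encodes a basic leucine zipper transcription factor. Of the ErbB2 mutants, 3 were flox/flox and 2 null/flox, and of the Maf mutants 2 were flox/flox and 3 null/flox. Arrays of a group correlated with each other at 0.958 to 0.995.

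The comparison of ErbB2 mutants with their controls asked which genes depend on ErbB2 in the early postnatal nerve. Lipid synthesis genes were lower in the mutants. Of the cholesterol synthesis genes, 16 of the 17 measured fell, with a median log2 fold change of −0.42. In addition 12 of the 16 genes of fatty acid synthesis and desaturation fell, with a median of −0.26. Of 17 genes for myelin and paranodal proteins 9 fell, led by Pmp2, a lipid-binding protein of peripheral myelin (2.56-fold), and Gjb1, a gap junction protein of Schwann cells (2.03-fold). Of 20 macrophage genes 6 rose, as did 6 of 21 genes of immature Schwann cells. The calls on these 3 lists were lost with an estimated correlation (adjusted p = 0.144, 0.338 and 0.430) and held with fry (adjusted p = 7.24e-05, 0.00884 and 0.0118). In total 1893 of 19938 genes changed, of which 1173 were higher and 720 lower, but among the 31 genes that changed at least 2-fold 28 were lower.

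Erbb2 itself was 0.31 (SE 0.10) higher on the log2 scale in ErbB2 mutants (adjusted p = 0.0489), with an SD of 0.30 among the mutants against 0.04 among the controls. The labels do not say which exons are floxed, so this probe set, which reads the whole transcript, does not measure the deletion. The call was lost when most single arrays were left out (adjusted p up to 0.164). Erbb3, its partner receptor, rose by 0.31 (SE 0.04, adjusted p = 3.28e-05). Erbb4, another neuregulin receptor, fell by 2.17 (SE 0.11, adjusted p = 1.09e-11). Maf fell by 0.45 (SE 0.12, adjusted p = 0.0133).

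In the cholesterol list, the lowest adjusted p values belonged to Tm7sf2, a sterol reductase, which fell by 0.85 (SE 0.06, adjusted p = 1.01e-08), and to Hmgcs1, the HMG-CoA synthase, which fell by 0.54 (SE 0.04, adjusted p = 1.48e-08). Lss, the lanosterol synthase, fell by 0.77 (SE 0.06, adjusted p = 3.08e-08). Nsdhl, a sterol dehydrogenase, fell by 0.41, and Sqle, the squalene epoxidase, fell by 0.36. The same count, 16, fell when adjusted over the list alone. The list was lower by camera (adjusted p = 1.34e-32), also with an estimated correlation (adjusted p = 0.00263). Its mean per array was lower in all 5 mutants than in any control (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0397). In the fatty acid list, the elongase Elovl7 fell by 1.14 (SE 0.07), and malic enzyme Me1 fell by 0.83 (SE 0.07). The acetyl-CoA synthetase Acss2 fell by 0.68 (SE 0.06) and the desaturase Scd1 fell by 0.53 (SE 0.04). Adjusted over the list alone, 13 of its genes fell, and camera called it lower (adjusted p = 7.97e-23, and adjusted p = 0.00179 with an estimated correlation). Its mean per array was lower in all 5 mutants (exact permutation adjusted p = 0.0397). Of 12 measured genes that control sterol supply, 3 fell, among them the SREBP escort protein Scap (−0.23). The 1 that rose was Lpin1, a phosphatidate phosphatase, by 0.43, and 8 did not pass, with no call for the list (adjusted p = 0.107). Of the 8 sterol efflux genes, 2 fell, including the cholesterol exporter Abca1 (−0.23), and 6 did not pass (list adjusted p = 0.306).

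**Figure D1:**
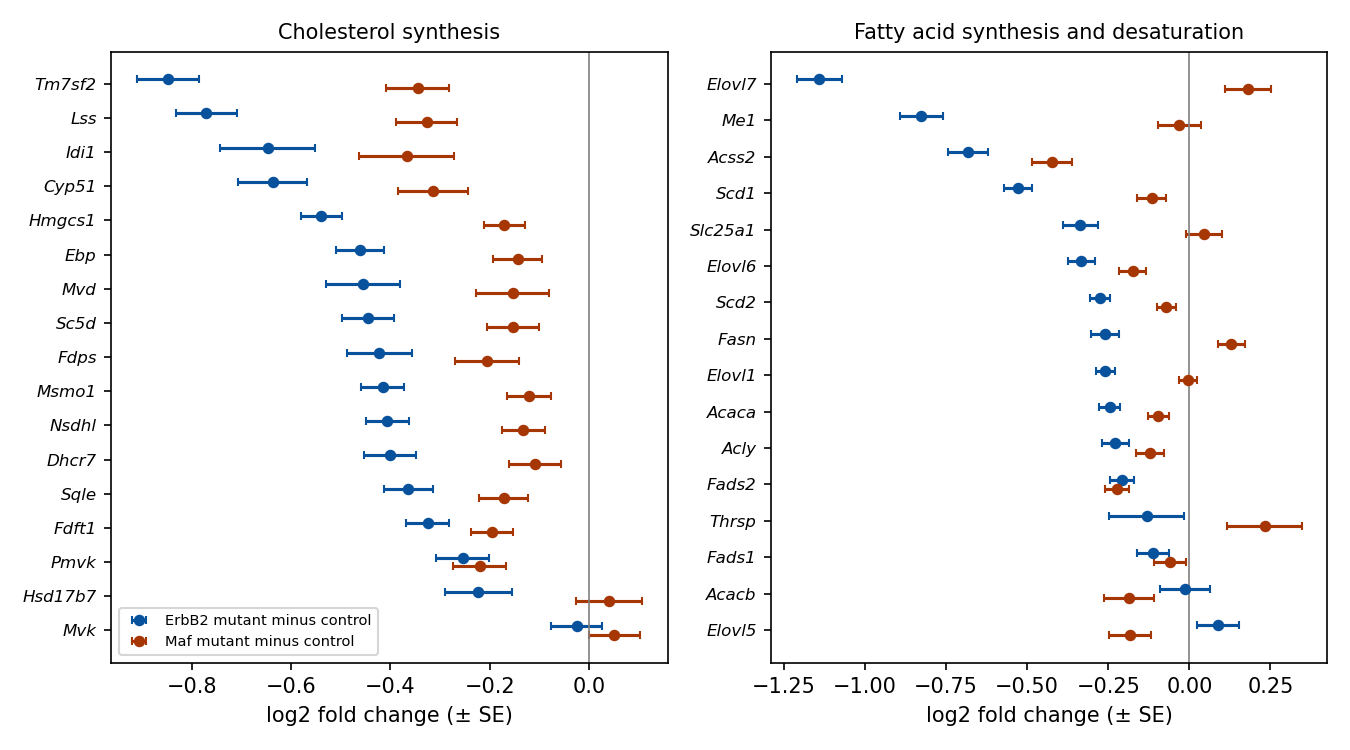
Log2 fold change, mutant minus control, with its standard error as a bar, for each measured gene of cholesterol synthesis and of fatty acid synthesis, in the ErbB2 comparison (blue) and the Maf comparison (brown), with 5 arrays per group. In the ErbB2 comparison 16 of 17 and 12 of 16 genes fell, and in the Maf comparison 8 of 17 and 3 of 16.

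Of the 17 measured genes for myelin and paranodal proteins, 9 fell and 8 did not pass in ErbB2 mutants. In this list 10 fell and 1 rose when adjusted over the list alone. Pmp2 fell by 1.36 (SE 0.06, adjusted p = 1.20e-12) and Gjb1 fell by 1.02 (SE 0.09, adjusted p = 2.15e-07). Mbp, myelin basic protein, fell by 0.19 (SE 0.03) and Dusp15, a phosphatase of myelinating cells, fell by 0.34 (SE 0.05). The list was lower by camera (adjusted p = 4.22e-10), a call that did not hold at adjusted p = 0.144 with an estimated correlation. Its mean per array was lower in the mutants (exact permutation p = 0.00794, adjusted p = 0.0397). Of 12 genes of myelin sphingolipid synthesis, 3 fell, namely the galactosylceramide synthase Ugt8a (−0.42), the ceramide synthase Cers2 (−0.36) and the desaturase Degs1 (−0.20), and 9 did not pass (list adjusted p = 0.00141, and adjusted p = 0.338 with an estimated correlation).

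Of 15 transcription factors of myelinating Schwann cells, 3 rose, 2 fell and 10 did not pass, with no call for the list (adjusted p = 0.235). Nab1, a corepressor that binds Egr2, fell by 0.62 (SE 0.06, adjusted p = 2.38e-07), and Pou3f1, a factor of promyelinating cells, rose by 0.50 (SE 0.05, adjusted p = 1.75e-06), as did its relative Pou3f2 by 0.36, of which a second probe set did not pass (0.16, adjusted p = 0.827). Egr2 fell by 0.24 (SE 0.07, adjusted p = 0.0293) and Sox10 rose by 0.17 (SE 0.05, adjusted p = 0.0433), both calls that were lost without most single arrays (adjusted p up to 0.0858 and 0.123). Of 21 genes of immature and injury-type Schwann cells, 6 rose and 15 did not pass. When adjusted over the list alone, 7 rose and 1 fell. Those that rose included the matrix protein tenascin C, Tnc, by 0.77 (SE 0.13) and the immediate early factor Egr3 by 0.53 (SE 0.09). Others were the differentiation inhibitor Id2 by 0.43 (SE 0.05) and the adhesion molecule Ncam1 by 0.28 (SE 0.06). Camera called this list higher at adjusted p = 0.0427, which was lost without any of 5 single arrays, ErbB2 mutants 4 and 5 and ErbB2 controls 3, 4 and 5 (adjusted p up to 0.0685), and at adjusted p = 0.430 with an estimated correlation. Its mean per array was higher in all 5 mutants than in any control (exact permutation p = 0.00794, adjusted p = 0.0397). Of 12 genes of non-myelinating Schwann cells, 4 rose, including the adhesion molecule Chl1 by 0.46, Cdh2 (N-cadherin) by 0.29 and the BMP antagonist Sostdc1 by 0.29, and 8 did not pass (list adjusted p = 0.00790, and adjusted p = 0.487 with an estimated correlation).

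Of the 31 cell cycle genes, 3 rose and 28 did not pass in ErbB2 mutants, and 7 rose when adjusted over the list alone. Mcm7, part of the replicative helicase, rose by 0.42 (SE 0.08) and the cyclin Ccnd1 rose by 0.24 (SE 0.06). All but 1 of these genes had a positive log2 fold change, with a median of 0.29. The list was higher by camera (adjusted p = 1.04e-06), but not at adjusted p = 0.490 with an estimated correlation. Its mean per array did not pass by exact permutation (adjusted p = 0.0902). ErbB2 mutant 1 stood at 9.89 log2, below the control mean of 9.94, and the other mutants at 10.23 to 10.40. Among 24 genes of ErbB receptors, their ligands and MAPK feedback, 5 rose, 2 fell and 17 did not pass, without a call for the list (adjusted p = 0.519). Besides Erbb3 and Erbb4, the MAPK phosphatase Dusp4 rose by 0.63 and the receptor inhibitor Errfi1 fell by 0.29. Of 10 genes of the Maf family and its partners, the BACH repressors Bach1 and Bach2 rose by 0.25 and 0.27. Maf was the 1 that fell, and 7 did not pass (list adjusted p = 0.540). Of 22 genes of the amino acid and ER stress response, 1 rose, the ER chaperone Sdf2l1 by 0.41. The 1 that fell was the amino acid transporter chain Slc3a2 (−0.19), a call lost without most single arrays (adjusted p up to 0.101), and 20 did not pass (list adjusted p = 0.906). Of 17 glycolysis genes, 1 fell, the aldolase Aldoc (−1.06, SE 0.12), and 16 did not pass (list adjusted p = 0.109).

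Of 20 macrophage genes, 6 rose in ErbB2 mutants and 14 did not pass, with 10 higher when adjusted over the list alone. Examples were Mpeg1, a pore-forming protein of macrophages, by 0.44, the lysosomal protein Laptm5 by 0.31 and cathepsin S, Ctss, by 0.30 (list adjusted p = 1.54e-05, and adjusted p = 0.338 with an estimated correlation). The mean of the macrophage list per array did not pass by exact permutation (adjusted p = 0.0595). Of 12 endothelial genes 1 fell, the tight junction protein Cldn5 (−0.25), and 11 did not pass, with a list median of −0.11. The list's adjusted p of 0.0181 was lost at adjusted p = 0.490 with an estimated correlation, and without ErbB2 mutant 1, ErbB2 control 1 or ErbB2 control 4 (adjusted p up to 0.105). In the perineurium list 2 of 10 rose, the junction scaffold Tjp1 by 0.26 and the keratin Krt19 by 0.26 (list adjusted p = 0.122). In the neuron and axon list 2 of 10 rose, the intermediate filaments peripherin, Prph, by 0.29 and neurofilament light chain, Nefl, by 0.48. Camera gave no call for this list (adjusted p = 0.109), while its mean per array was higher in all 5 mutants than in any control (exact permutation p = 0.00794, adjusted p = 0.0397). The fibroblast list had 1 of 13 lower, lumican, Lum (−0.30) (list adjusted p = 0.109). The pericyte and smooth muscle list had 1 of 10 higher, Pdgfrb by 0.18, and 1 lower, Cspg4 (−0.24) (list adjusted p = 0.578). No gene passed among 9 of T and B lymphocytes, 13 of neutrophils and mast cells, 11 of adipocytes, 19 of skeletal muscle or 3 of blood, and these lists had adjusted p of 0.961, 0.541, 0.759, 0.422 and 0.906.

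Among single genes without overlap between mutants and controls, as the rule for naming required, the largest increases after ErbB2 mutation were in 3 genes. They were Myo3a, a myosin (3.55-fold), Gad2, a glutamate decarboxylase (3.37-fold), and Cacng3, an auxiliary subunit of AMPA receptors (2.91-fold). Increases of 0.81 to 0.96 log2 followed in the glutamine transporter Slc38a1, the collagenase Mmp8, the O-glycosylation enzymes Galnt3 and Galnt6, the netrin receptor Unc5c, the docking protein Dok5 and the axonemal dynein Dnah9. A second probe set of Slc38a1 rose by 0.27 and did not pass (adjusted p = 0.102). The largest decreases were in Fam107a, an actin-associated protein (5.31-fold), Erbb4 (4.49-fold), the amino acid transporter Slc6a15 (4.45-fold), Ddn, which encodes dendrin (3.65-fold), and H2-DMa, which helps load MHC class II molecules (3.52-fold). Chst2, a carbohydrate sulfotransferase, the lectin receptor gene Klrb1a, Serpinb6b, Ankfn1 and the Wnt receptor ligand Ndp fell by 1.49 to 1.76 log2.

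In this comparison 2455 of all 19938 genes had no overlap between the 5 mutant and 5 control values, which chance gives for 0.794% of genes; 1607 of them were among the 1893 changed genes. The count of changed genes was 2896 with only these groups in the fit, 4490 with array weights and 1042 at an adjusted p under 0.01. The calls on Abca1, Pou3f2, Krt19, Cldn5, Cspg4 and Pdgfrb were each lost without at least 1 single array, with adjusted p up to 0.0676, 0.0616, 0.0992, 0.0603, 0.0585 and 0.137.

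The comparison of Maf mutants with their controls asked which genes depend on Maf. Maf fell 3.06-fold, and 8 of 17 cholesterol synthesis genes fell, with a list median of −0.17. None of the 17 myelin and paranodal protein genes fell, and 2 rose. Of 12 endothelial genes 2 fell and 10 did not pass, with a list median of −0.23. The calls on the cholesterol and endothelial lists were lost with an estimated correlation (adjusted p = 0.285 and 0.380) and held with fry (adjusted p = 0.0111 and 0.0362). In total 999 genes changed, of which 589 were higher and 410 lower. With each array centred on its median these counts became 477 and 529, so the balance of directions rests on the scaling. Of the 26 genes that changed at least 2-fold, 13 were higher and 13 lower.

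**Figure D2:**
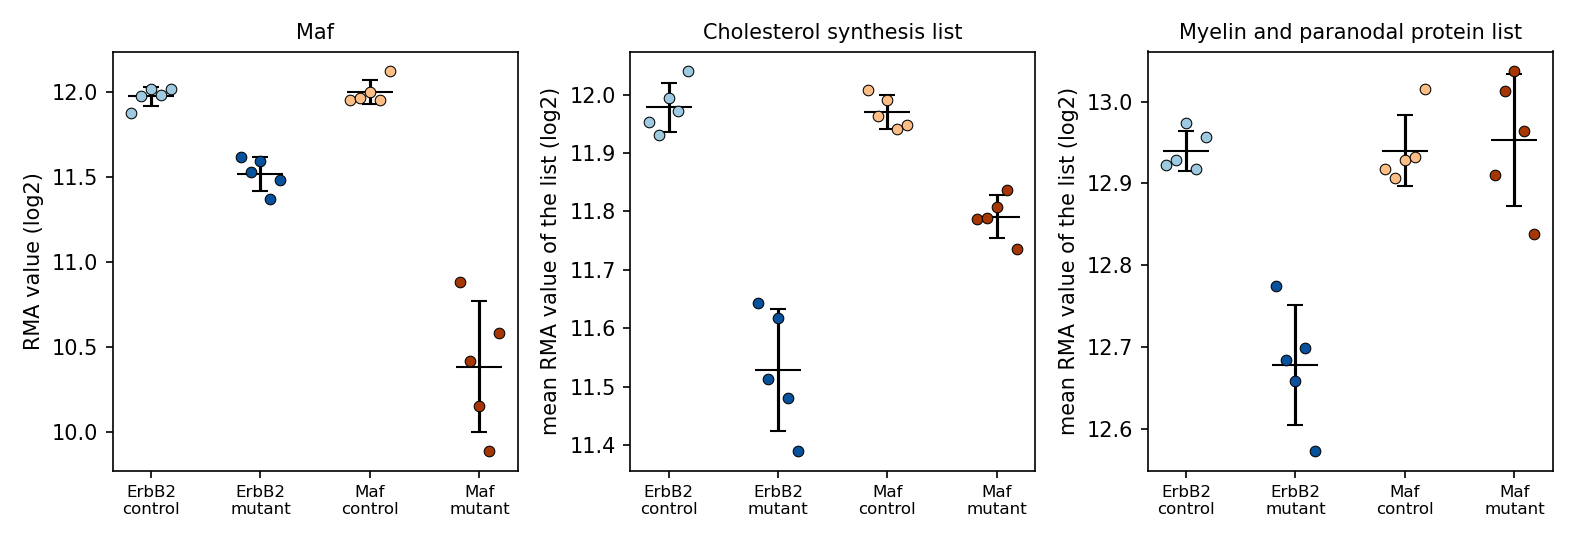
Log2 value of Maf and mean log2 value of the cholesterol synthesis list and of the myelin and paranodal protein list in each array of the 4 groups; each point is 1 animal, and bars show the group mean and SD of 5 animals. Maf averaged 10.39 in Maf mutants and 11.52 in ErbB2 mutants, against 12.00 in Maf controls and 11.97 in ErbB2 controls.

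Maf fell by 1.61 (SE 0.12, adjusted p = 9.41e-09) in Maf mutants, while Erbb2 differed by 0.08 (SE 0.10, adjusted p = 0.792). In the cholesterol list Tm7sf2 fell by 0.34 (SE 0.06, adjusted p = 0.00158) and Lss fell by 0.33 (SE 0.06, adjusted p = 0.00213). Cyp51, the lanosterol demethylase, fell by 0.31 (SE 0.07, adjusted p = 0.00862), and Fdft1, the squalene synthase, fell by 0.20 (SE 0.04, adjusted p = 0.00718). Hmgcs1 fell by 0.17 (SE 0.04, adjusted p = 0.0155), a call lost without Maf control 1 (adjusted p = 0.0567). Sqle fell by 0.17 (SE 0.05, adjusted p = 0.0487), a call lost without most single arrays (adjusted p up to 0.137). When adjusted over the list alone, 13 of the 17 fell. Camera called the list lower (adjusted p = 7.50e-12), not at adjusted p = 0.285 with an estimated correlation. Its mean per array was lower in all 5 mutants (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0661). Of the 16 fatty acid genes 3 fell, Acss2 (−0.42), the desaturase Fads2 (−0.22) and the elongase Elovl6 (−0.17), and 13 did not pass. Adjusted over the list alone 9 fell and 2 rose (list adjusted p = 0.000767, and adjusted p = 0.380 with an estimated correlation). Fasn, the fatty acid synthase, differed by 0.13 (SE 0.04, adjusted p = 0.0854). Of 8 sterol efflux genes 2 fell, Abca1 (−0.31) and the phospholipid enzyme Lpcat3 (−0.16) (list adjusted p = 0.192). None of 12 genes of sterol control passed (list adjusted p = 0.971).

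Among myelin and paranodal proteins, 2 of 17 rose in Maf mutants, the plasmolipin gene Pllp by 0.25 (SE 0.06) and the claudin Cldn19 by 0.14 (SE 0.03), while 15 did not pass. The call on Cldn19 was lost without any of 5 single arrays (adjusted p up to 0.0618). Adjusted over the list alone 5 rose and 4 fell (list adjusted p = 0.889). Of 12 sphingolipid genes 2 rose, the sialyltransferase St3gal5 and the reductase Kdsr, each by 0.17, both lost without most single arrays (adjusted p up to 0.105 and 0.107; list adjusted p = 0.621). Egr2 and Sox10 differed by 0.14 and 0.13 and did not pass (adjusted p = 0.343 and 0.205). Of 15 transcription factors of myelinating cells 4 rose and 11 did not pass (list adjusted p = 0.0514). The firmest was Pou3f1, by 0.28 (SE 0.05, adjusted p = 0.00211), while Tead1, Zeb2 and Nr4a2, which rose by 0.17, 0.14 and 0.24, were lost without any of 5 single arrays each (adjusted p up to 0.0746, 0.0678 and 0.0898). A second probe set of Tead1 rose by 0.18 (adjusted p = 0.00457). In the immature Schwann cell list Id2 rose by 0.25, Tnc fell by 0.78 (SE 0.13, adjusted p = 0.000598) and 19 of 21 did not pass (list adjusted p = 0.620). None of the 12 genes of non-myelinating Schwann cells passed (list adjusted p = 0.0872).

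Of 31 cell cycle genes 1 fell in Maf mutants, the S-phase factor E2f1 (−0.36, SE 0.07), and 30 did not pass. Of all 31, 30 had a negative log2 fold change, with a median of −0.26 (list adjusted p = 2.32e-08, and adjusted p = 0.664 with an estimated correlation). The mean of the cell cycle list per array did not pass by exact permutation (adjusted p = 0.624). Of 24 genes of ErbB signalling Dusp4 rose by 0.99 (SE 0.09) and the feedback inhibitor Spry4 fell by 0.40 (SE 0.10). The call on Spry4 was lost without any of 4 single arrays (adjusted p up to 0.0695; list adjusted p = 0.152). In the Maf family Bach2 rose by 0.35 (SE 0.07) and only Maf fell (list adjusted p = 0.889). In the stress list Psph, an enzyme of serine synthesis, rose by 0.23 and 21 of 22 did not pass (list adjusted p = 0.709). Of 17 glycolysis genes 2 fell, Aldoc (−0.69) and the phosphofructokinase Pfkp (−0.33) (list adjusted p = 0.146).

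Among cell type lists, 2 of 12 endothelial genes fell in Maf mutants, Cldn5 and Esam, both for endothelial junction proteins (−0.24 and −0.31). The Cldn5 call was lost without any of 6 single arrays (adjusted p up to 0.128). Adjusted over the list alone 10 of 12 endothelial genes fell (list adjusted p = 6.89e-07, and adjusted p = 0.380 with an estimated correlation), and the list mean per array did not pass by exact permutation (adjusted p = 0.317). Of 13 fibroblast genes 1 fell, the receptor Pdgfra (−0.21). The list's adjusted p of 0.0121 was lost at adjusted p = 0.664 with an estimated correlation and without Maf mutant 3 or Maf mutant 4 (adjusted p up to 0.107). Of 10 neuron and axon genes the ubiquitin hydrolase Uchl1 fell by 0.29, lost without most single arrays (adjusted p up to 0.137; list adjusted p = 0.738). No gene passed among macrophages, T and B lymphocytes, neutrophils and mast cells, perineurium, pericytes and smooth muscle, adipocytes, skeletal muscle or blood, whose lists had adjusted p of 0.103, 0.318, 0.490, 0.395, 0.148, 0.247, 0.395 and 0.970.

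The largest increases in Maf mutants were in Gad2 (4.82-fold), Myo3a (4.52-fold), Tyrp1, an enzyme of melanin synthesis (2.78-fold), Ankub1 (2.77-fold), Abca12, a lipid transporter of the skin (2.73-fold), and the contactin Cntn6 (2.57-fold). The receptor tyrosine kinase Ephb1, the secreted protein Nell2, the neuropeptide neuromedin U, Nmu, and Piwil4, an Argonaute family member, rose by 1.13 to 1.21 log2. A second probe set of Ephb1 rose by 0.35 (adjusted p = 0.0119). The largest decreases were in Ddn (4.60-fold), Fam107a (4.03-fold), Chst2 (3.85-fold), Ankfn1 (3.11-fold) and Maf. The palmitoyltransferase Zdhhc2, the receptor Epha6, the glycolipid enzyme B3gnt5, Cttnbp2 and the cilium gene Cfap100 fell by 1.11 to 1.26 log2.

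Of all 19938 genes, 826 had no overlap between mutants and controls, 633 of them among the 999 changed genes. The count of changed genes was 1865 without Maf mutant 5 and 4095 with flox/flox mutants only. It was 457 with only these groups in the fit, where the spread was not shared with the ErbB2 line. Maf mutants 4 and 5 lay at opposite ends of the first component of variation within groups, and 1352 genes changed without both.

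Both mutations were then compared to ask whether they act on common genes. In both comparisons 422 genes changed, 374 in the same direction, a count that was 248 with only the groups of a comparison in the fit, 673 with array weights and 35 at a fold of at least 1.5. Of the 374, 201 rose in both, where independent lists would share 34.7, and 173 fell in both, where they would share 14.8. The genes with the largest shared increase were Myo3a, Gad2, Piwil4, Tyrp1 and Mamdc2, the last by 0.65 and 0.86. Those with the largest shared decrease were Fam107a, Ddn, Chst2, Ankfn1 and the lactase-like gene Lctl, which fell by 1.27 and 1.02. The cholesterol synthesis genes Tm7sf2, Lss, Hmgcs1, Cyp51 and Fdft1 fell in both. Across all genes the log2 fold changes correlated at 0.237 (Pearson) and 0.101 (Spearman), values over genes that are not independent. This correlation was no larger than that of other groupings of the same arrays, 27 of 100 of which reached it, the real one included.

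**Figure D3:**
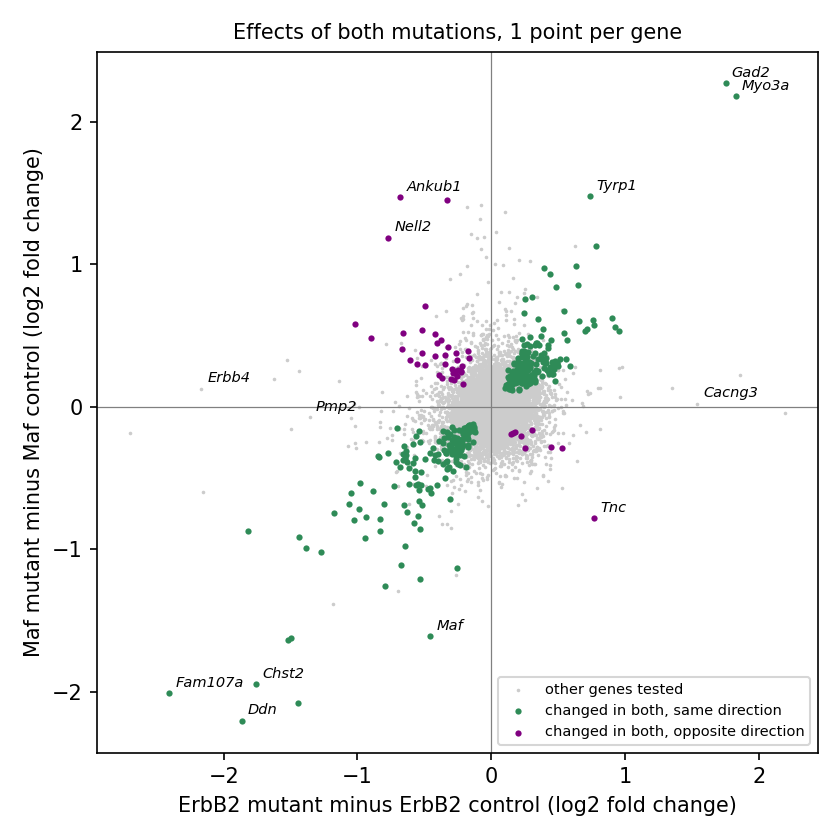
Log2 fold change in Maf mutants (vertical axis) against that in ErbB2 mutants (horizontal axis) for 19938 genes, 1 point per gene. Genes changed in both comparisons are green where the directions match (374 genes) and purple where they are opposite (48 genes).

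The difference between both effects was tested directly, and 551 genes had a different effect, 214 with a higher and 337 with a lower log2 fold change after ErbB2 mutation. The largest differences with a lower ErbB2 effect were in Erbb4 (−2.29, SE 0.15), Ankub1 (−2.15, SE 0.18), Nell2 (−1.95, SE 0.15), Serpinb6b (−1.86, SE 0.15) and Klrb1a (−1.82, SE 0.10). Ankub1 and Nell2 moved in opposite directions, with log2 fold changes of −0.68 and −0.77 in ErbB2 mutants and of 1.47 and 1.19 in Maf mutants. The largest with a higher ErbB2 effect were in Tnc (1.55, SE 0.18), which rose in ErbB2 and fell in Maf mutants, Cacng3 (1.52, SE 0.22), Maf (1.16, SE 0.16), B3gnt5 (0.92, SE 0.16) and Slc38a1 (0.90, SE 0.19). Cholesterol synthesis genes fell further in ErbB2 mutants, with a median difference of −0.29 (adjusted p = 4.87e-15, and adjusted p = 0.0713 with an estimated correlation). So did fatty acid genes, with −0.23 (adjusted p = 3.68e-12, and adjusted p = 0.0390 with an estimated correlation). The myelin protein list differed by −0.18 (adjusted p = 1.62e-10, and adjusted p = 0.132 with an estimated correlation). Cell cycle genes differed by 0.54 (adjusted p = 1.99e-17, and adjusted p = 0.191 with an estimated correlation) and macrophage genes by 0.25 (adjusted p = 4.02e-08, and adjusted p = 0.157 with an estimated correlation). Of 422 genes changed in both comparisons, 48 moved in opposite directions and 72 differed between the effects. The count of 551 was 1019 without Maf mutant 5, 1862 with array weights, 302 with a replicate block and 238 at an adjusted p under 0.01.

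Mutants with 1 null and 1 floxed allele were compared with flox/flox mutants of the same line to ask whether the null allele adds to the change. Among ErbB2 mutants, 2 against 3 arrays, limma called 2 genes, and 1330 had an unadjusted p under 0.05. The called genes were Cacng3, 0.85 higher (SE 0.12, adjusted p = 0.0140) in null/flox mutants, and the uncharacterised C330024D21Rik, with a log2 fold change of −0.58 (SE 0.09, adjusted p = 0.0288), the latter named after its value was seen. Among Maf mutants, 3 against 2 arrays, 4191 genes differed, 1821 higher and 2370 lower in null/flox mutants, with a median over all genes of −0.09. Maf itself was 0.61 (SE 0.10, adjusted p = 0.00135) higher in null/flox than in flox/flox Maf mutants. The count of 4191 was 391 without Maf mutant 4, 1359 without Maf mutant 5, and 505 with each array's interquartile range as a covariate. Covariates for Y-linked expression or the 2-level factor raised it. Xist was high in flox/flox Maf mutants 3 and 4 and in null/flox mutant 5, and low in null/flox mutants 1 and 2. Sex as read from Xist thus ran partly with the allele class.

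Both control groups were compared to ask how far the lines differ without a mutation. Limma called 0 genes, and 0 had an unadjusted p under 0.05. This count carries no information about the lines, since an exact linear relation tied the means of both lines together in the deposited values. The control means lay within 1 standard error of each other in 99.97% of probe sets, where chance gives 65.3%.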

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

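The explanations weighed in this part were set against results already seen, except the other splits of the control arrays. The tests of the difference of effects and the covariate for Y-linked expression had been planned before the data were examined.

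The shared changes are the first pattern weighed: 374 genes changed in the same direction in both mutants. Other splits of the ErbB2 arrays call few genes, so as many genes of lowest p were taken in each split as the real comparisons call. Then 1 of 100 splits gave as many shared genes, the real one, and the highest other gave 198. This is the smallest share that 100 splits can give, and it makes chance unlikely. DNA carried along with the Egr2-Cre allele would place these genes around Egr2, but only 0.802% of them lay among the 100 tested genes nearest to it, 3 genes where 1.88 were expected at the overall rate. A loss of Maf transcript passed on in proportion to its fall, 0.282 times as large in ErbB2 as in Maf mutants, would leave the other genes at a like ratio. Their median ratio was 1.03, with quartiles of 0.784 and 1.35, over 373 genes picked because they passed in both comparisons, which raises it. In data simulated at 0.431, the ratio for Maf plus 2 standard errors, and picked the same way, the median ratio was 0.558 in the middle draw and 0.761 in the highest, with noise taken from splits of the ErbB2 arrays. The same data held 170.5 shared genes in the middle draw and 388 in the highest, against 373 seen. The number seen lay near the top of that range but within it, and how many draws reached it was not counted. The number alone therefore does not rule out such a loss. By the ratio, such a loss is not the whole cause of the set, as far as the Maf probe set measures it, since the labels do not say which exons are floxed. Gene by gene, 32 of the 373 lay beyond 0.431 by a test with Bonferroni adjustment over all genes. Carriage of Egr2-Cre itself cannot be told apart from a response common to both mutations, because 0 controls carried it. A common response of the nerve to either mutation stays open as a hypothesis.

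The second pattern is the 4191 genes that differed between Maf mutants with and without a null allele. With each array's interquartile range as a covariate the count was 505, so much of it may come from differences in array contrast, of which Maf mutants 4 and 5 were the extremes. The null allele stays open. Maf was 0.61 higher in null/flox mutants (10.63 against 10.02 log2), but the labels do not say which part of the gene this allele lacks. The level of each array's contrast runs with the genotype, and so in part does sex as read from Xist. The 10 splits of the 5 mutants are too few for a share under 0.05; the real split, 1 of 10 with as many genes, gave 4191 and the highest other 555.

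The third pattern is the fall of cholesterol synthesis genes in ErbB2 mutants, median −0.42. A lower share of Schwann cells would lower genes of myelin proteins, which these cells alone make in the nerve, at least as far, but 12 of 17 such genes lay above −0.42 by more than 2 standard errors, and 2 lay at or below it. With the array's interquartile range as a covariate, for differences in array contrast, the list median was −0.41, and with Y-linked expression as a covariate, since 4 of 5 ErbB2 mutants but 2 of 5 controls had low Xist, it was −0.43. Each of these values argues against its explanation as the whole cause. Carriage of Egr2-Cre itself cannot be told apart from the loss of ErbB2, because all ErbB2 mutants and no controls carried it. The list also fell in Maf mutants, which carried the same Cre, though less far (median −0.17). A response of Schwann cells to the loss of ErbB2 is a candidate explanation that no test here measured.

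For the counts themselves, 1 of 100 splits gave as many changed genes as the 1893 of the ErbB2 comparison, the real one. The highest other gave 1, which makes chance unlikely. Other splits mix mutants with controls, which adds the mutant effect to the spread within groups and can lower their counts. For the 999 of the Maf comparison 3 of 100 splits gave as many genes, and for the 551 of the difference of effects 3 of 100. These shares are under 0.05, but some other splits gave more genes than the real one. The counts alone therefore do not exclude chance in these 2 cases. The highest other values, 6250 and 2882, point to a structure of the arrays: the split with 6250 set Maf mutants 1, 3 and 4 with Maf controls 3 and 5, and the first component within groups, 44.6% of that variance, correlated with the interquartile range. With that range as a covariate the Maf count was 1578. For the correlation of effects, 0.237, 27 of 100 splits were as large and the highest other was 0.502, so chance cannot be excluded. For both control groups the count was 0, which each of the 100 splits reaches by necessity (highest other 2), so the splits decide nothing there.

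Samples far from the rest of their group were sought in 292 groups of 5, of which 18 were found where chance gives 14.6; the values are the gap to the nearest sample divided by the group's range. Among list means the ratio was 0.945 for neutrophils and mast cells in ErbB2 mutant 5, which stood at 8.90 log2 against 7.87 to 7.93 in the other ErbB2 mutants, and 0.873 for the same list in Maf control 2. It was 0.759 for fatty acid synthesis in ErbB2 mutant 5, 0.739 for sterol efflux in ErbB2 mutant 1 and 0.821 for perineurium in Maf mutant 5. In Maf control 5 it was 0.764 for myelin proteins and 0.767 for ErbB signalling, and in Maf control 2 it was 0.719 for glycolysis. Among genes, Maf control 5 stood apart for Maf (0.739), Egr2 (0.759) and Galnt6 (0.734), Maf control 1 for Gad2 (0.809), Maf control 2 for Cntn6 (0.798) and Maf control 3 for Klrb1a (0.882). ErbB2 mutant 1 stood apart for Galnt3 (0.744), ErbB2 mutant 5 for Klrb1a (0.803), ErbB2 control 2 for Dok5 (0.770) and Maf mutant 5 for Nell2 (0.859).

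Effects that differed between both mutations by the test of the difference are given as the ErbB2 effect minus the Maf effect. Besides the values of Maf (1.16), Tnc (1.55), Cacng3 (1.52), B3gnt5 (0.92) and Slc38a1 (0.90), it was positive for Cttnbp2 (0.88), Galnt6 (0.68), Galnt3 (0.68), Epha6 (0.67) and Dnah9 (0.55). It was negative for Erbb4 (−2.29), Ankub1 (−2.15), Nell2 (−1.95), Serpinb6b (−1.86), Klrb1a (−1.82), Abca12 (−1.77), Slc6a15 (−1.55), Ephb1 (−1.37), Ndp (−1.34), Nmu (−1.29) and Cntn6 (−1.26). Smaller negative differences were found for H2-DMa (−0.95), Tyrp1 (−0.73), Egr2 (−0.37) and Hmgcs1 (−0.37). Among lists the median difference was −0.29 for cholesterol synthesis, −0.23 for fatty acid synthesis, −0.18 for myelin proteins, −0.15 for myelin sphingolipids, 0.11 for immature Schwann cells, 0.18 for non-myelinating Schwann cells, 0.17 for perineurium, 0.25 for macrophages and 0.54 for the cell cycle. With an estimated correlation the difference for fatty acid synthesis held (adjusted p = 0.0390) and the others were lost, those from sphingolipids to perineurium at adjusted p = 0.163, 0.191, 0.163 and 0.362.

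Probe sets outside the comparisons also differed between mutants and controls. In the ErbB2 comparison 121 of 1621 probe sets with several gene symbols and 531 of 12146 without a listed gene passed, and in the Maf comparison 67 and 150 did.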

How the results depend on the processing

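The values with an interquartile range covariate, with the 2-level factor and without Maf mutants 4 and 5 were added after the data had been seen. No call on a named gene or list changed direction, but the balance of the Maf comparison did, from 589 higher and 410 lower to 477 and 529 with each array centred on its median. Of the 154 calls on named genes, 126 held without each array in turn and 120 under all other settings but stricter thresholds, with 87 lost at a fold of at least 1.5 and 40 at an adjusted p under 0.01. Of the 14 calls on lists 11 held without each array, and 12 of the 14 were lost with an estimated correlation. With fry in place of camera 4 of the 14 were lost, and 2 lists without a call by camera passed. The cause of the changes below was not tested, except where stricter thresholds or fewer arrays or genes make it plain. With only the groups of a comparison in the fit, 2896 genes changed in the ErbB2 and 457 in the Maf comparison, 248 in the same direction in both, and 0 and 616 between allele classes of ErbB2 and Maf mutants. With arrayWeights these counts were 4490, 1693 and 673, with 1862 for the difference of effects and 728 for the Maf allele classes. With a fold of at least 1.5 they were 129, 94 and 35, with 126 for the difference and 1 and 429 for the allele classes. At an adjusted p under 0.01 they were 1042, 508 and 199, with 238 for the difference and 0 and 874 for the allele classes. With a replicate block the difference gave 302 and the allele classes 0 and 1. With flox/flox mutants only, the Maf comparison gave 4095 and the difference 1252. The allele classes gave 1 and 2034 genes with the skeletal muscle list mean as a covariate, 0 in ErbB2 mutants for genes above the array median in at least 5 arrays, and 6753 in Maf mutants with the Y-linked mean as a covariate. With the interquartile range the counts were 3143, 1578, 618 for shared genes and 505 for Maf allele classes, and the latter was 8237 with the 2-level factor of the linear relation. Without Maf mutants 4 and 5 the difference gave 870 and the Maf allele classes 168. Leaving out 1 array gave 698 to 1865 in the Maf comparison and 402 to 1019 for the difference, both highest without Maf mutant 5. It gave 391 to 6134 for the Maf allele classes, lowest without Maf mutant 4 and at 1359 without Maf mutant 5, and 0 to 3 for those of ErbB2, with 0 without ErbB2 mutants 1, 2 or 4 and 1 without ErbB2 mutant 3.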

Other observations

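The tests of Ciart and Tyrp1 in this part were written before their results were seen, and those of the relation between the lines after. The genes named in the next paragraphs were chosen after their values were seen.

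Of 6 genes known from Schwann cells, S100b and Cdh19 fell in both mutants. Erbb3 and Sox10 rose in ErbB2 mutants (0.31 and 0.17) and did not pass in Maf mutants, and Adgrg6 and Lgi4 passed in neither. Among other genes, Dhh, a hedgehog ligand that Schwann cells send to the developing perineurium, fell by 0.46 (SE 0.04, adjusted p = 8.29e-08) in ErbB2 mutants and by 0.57 (SE 0.04, adjusted p = 5.44e-09) in Maf mutants. S100b, a calcium-binding protein, fell by 1.44 and 0.91, and the cadherins Cdh19 and Cdh3 fell by 0.35 and 0.50 and by 0.99 and 0.72. Bmp7, a secreted growth factor, fell by 0.84 and 0.35. Sox4, a transcription factor of immature cells, rose by 0.49 and 0.30.

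The 48 genes that moved in opposite directions were mostly lower after ErbB2 and higher after Maf mutation, 39 of them, where independent lists would share 21.3; 9 went the other way, where they would share 24.1. The balance of directions in the Maf comparison rests on the scaling. The opposite set was not counted after centring or in other splits of the arrays, so the cause of its imbalance was not tested. The surface glycoprotein gene Cd24a had log2 fold changes of −0.51 in ErbB2 and 0.54 in Maf mutants, the phagocytic receptor gene Mertk of −0.28 and 0.25, the kinase gene Hipk2 of −0.18 and 0.39, and the guidance ligand gene Slit3 of −0.17 and 0.34. The protease Adamts5 had 0.45 in ErbB2 and −0.29 in Maf mutants. Gad2 and Myo3a, which led the shared increases, lie next to each other in the order of GRCm38.p6 with 1 listed gene between them, which is not protein-coding.

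Ciart, a repressor of the circadian clock, was lower in ErbB2 mutants (−0.66, adjusted p = 0.00268) and higher in Maf mutants (0.52, adjusted p = 0.0272). A different time of day at sampling might do this, and would move other clock genes with it, but 0 of 11 passed the test of the difference in the direction predicted, and 6 had the predicted sign. The output gene Dbp differed by −0.21 against −1.18 for Ciart.

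Tyrp1, which rose in both mutants, is an enzyme of melanocytes, and more melanocytes could raise it. None of 6 other melanocyte genes rose in either comparison (0), and Pmel, at 9.06 log2 on average, fell by 0.43 (adjusted p = 0.00893) in ErbB2 mutants. Tyr, Dct, Slc45a2 and Mlana averaged 6.31, 7.26, 7.69 and 8.27 log2, below the arrays' medians of 8.51 to 8.56. A small rise in these genes could therefore be missed.

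The control means of both lines were nearly equal, with an SD of their difference of 0.02 log2 over probe sets where the spread within groups gives 0.07. The refitted line term, with an SD of 9.40e-06, is in line with a term for the line that was subtracted before deposit. The 2-level factor read from the relation matched high Xist or high Y-linked expression in 17 of 20 arrays (Fisher's exact p = 0.00548), so it may be the sex of the animals, which the remaining 3 arrays leave open. High Xist was found in 1 of 5 ErbB2 mutants and in 3 of 5 animals of each other group.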
